A study of Bos grunniens with 24 samples.

How the data were processed

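Jejunal tissue of yak calves was sequenced in 24 libraries, 8 each from untreated controls (CON), calves challenged with enterotoxigenic Escherichia coli (ETEC) and calves given Pediococcus pentosaceus NQ0729 before the challenge (PET). Groups and replicate numbers came from the sample titles; the labels give no sex, age, batch or position along the jejunum. They call the samples replicate biosamples without naming the animals, so p-values measure the spread between these samples. Per the labels' protocols, RNA was extracted with TRIzol and its integrity checked, and the library text describes enrichment for small RNAs, although the table holds gene-level values. The aligner, counting tool, genome build and annotation are not given in the sources used here.

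Per the file headers, the authors gave a read count per gene and library, which are whole numbers without normalization. Per the file headers, the authors also gave FPKM, fragment counts scaled by gene length and by mapped fragments, for the same genes and libraries. The authors' deposited log2 fold changes and the deposited p-value and adjusted p-value columns cover the 3 comparisons, and their calls equal an adjusted p under 0.05 with at least a 2-fold change. The table lists 639 genes, each called by the authors in at least 1 comparison, of which 364 have an Ensembl identifier, 275 have none and 240 have a symbol. None of the identifiers matched the reference table used for names (assembly Bosgru_T2T1.0; 0 matches), so symbols and coordinates are those in the authors' table. Without a stated strand setting or handling of shared reads, genes that overlap or have near-identical copies are uncertain; this holds for USP9Y, which has an X-linked relative.

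Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr with the groups, 1 fit over all 3 groups), with Benjamini-Hochberg adjustment over the 578 genes that passed the filter and a threshold of 0.05; 61 genes were not tested. TMM presumes that most genes entered do not change, while the table holds only called genes. A second scaling therefore took each library's relative depth from its ratios of count to FPKM over genes with at least 20 counts. It was chosen after seeing the data, and the results of both scalings had been seen when TMM was kept as the main one, as set before. TMM moved the log2 fold changes against this second scaling by a median of 0.61 in ETEC vs CON, -0.63 in PET vs ETEC and -0.02 in PET vs CON. The authors' deposited table lay at a median of -0.57, 0.59 and 0.05 from the TMM values, and at 0.06, -0.01 and 0.05 from those of the second scaling. The sign of the log2 fold change differed between the scalings for 49, 99 and 23 of the 578 genes, and 0 genes were called by both with opposite signs. Falls in ETEC and rises in PET vs ETEC are thus smaller with TMM, and levels in FPKM do not depend on this choice.

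The genes named were chosen by a fixed rule: per comparison, the 6 largest rises and the 6 largest falls among called genes with a symbol and a mean of at least 1 FPKM, and up to 2 called members of each gene list, stopping at 18, with lists ordered by their smallest adjusted p. This gave 47 distinct genes, and results for 3 of them are not reported here. Of 40 gene lists fixed for the tissue, its cell types and the challenge, 21 had a member in the table, which holds 53 of their 1273 genes; only list members among the authors' called genes could be counted. Enrichment of lists was not tested, because the genes that the authors did not call are not analysed here. Means are given with SD over 8 libraries, and log2 fold changes with SE where stated. A gene without counts was set to a floor of 3 counts per library, which covers counting error only. The geometric mean of FPKM over 11 brush border genes (ANPEP, ENPEP, SLC10A2, SLC1A1, SLC26A3, SLC6A19, SLC23A1, SLC34A2, SLC7A9, CA4 and CA12, chosen after seeing the data as the members of 3 lists lower in ETEC with both scalings) used a pseudocount of 0.1.

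Pairs of libraries within a group were compared by a chi-square of their counts; over 84 pairs the smallest value per gene was 38.2, so none agreed within sampling noise. Each library was also fitted by non-negative weights of every pair of others (253 pairs, 511 genes with a mean of at least 20 counts outside the Y chromosome), and libraries with a residual below 0.8 of that of the best single library were set apart as close to a sum; this check was chosen after seeing the data. Shared libraries between comparisons were examined with 100 simulated sets of unchanged groups and with 70 splits of the shared group in sets of 4. Alternatives were DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), DESeq2 size factors in edgeR, no filter, only the groups compared, a 2-fold threshold, the replicate number as a block and leaving out each library; those added later were the second scaling, the 14 libraries not close to a sum, both together, and leaving out ETEC-8 with PET-8. On simulated counts with the real means and library sizes, 4-fold changes were recovered in 95.9%, 98.0% and 99.0% of changed genes for ETEC vs CON, PET vs ETEC and PET vs CON (617, 625 and 619 genes run), and 2-fold changes in 45.9%, 39.4% and 40.8%. Of the unchanged genes, 3 of 422, 3 of 427 and 2 of 423 were called. These simulated libraries were independent, with a capped spread and balanced rises and falls, so the rates need not hold for the real libraries. The authors' fold changes, limited in size, were also put in. Fitted values then lay at a median of 0.20, -0.42 and -0.48 from the true ones with TMM. With the second scaling, whose relative depths were used to simulate the counts, they lay at 0.01, 0.03 and -0.01. Each of these runs changed only the first-named group of a comparison, so the TMM shifts need not hold for the real libraries. In PET vs CON the real TMM values differed from those of the second scaling by a median of only -0.02. Plots and fits of libraries used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.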

Results

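Gene expression was measured by RNA sequencing in jejunal tissue of yak calves (Bos grunniens), the middle part of the small intestine. The 24 libraries fall into 3 groups of 8: untreated controls (CON), calves challenged with enterotoxigenic Escherichia coli (ETEC), a diarrhoea-causing bacterium, and calves given the lactic acid bacterium Pediococcus pentosaceus NQ0729 before the same challenge (PET). The table analysed here holds 639 genes, and in the authors' deposited table each of them was called in at least 1 of the 3 comparisons. Counts over the listed genes ranged from 299776 to 826249 per CON library, from 466708 to 863801 per ETEC library and from 475295 to 1209769 per PET library. The ratio of count to FPKM gave relative sequencing depths of 0.706 to 1.08 in CON, 0.833 to 1.47 in ETEC and 0.820 to 1.28 in PET. The first principal component of the listed genes held 39.7% of the variance and the second 21.2%.

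The libraries differed in ways that the group labels do not name. USP9Y, a Y-linked ubiquitin protease gene (ENSBGRG00000015615; chromosome Y, 985966 to 1142948), had 0 counts in all 8 CON libraries, in ETEC-8 and in PET-8, and 10.1 ± 4.46 FPKM in ETEC and 11.1 ± 5.59 in PET (SD, n = 8 each). Against a floor of 3 counts per library, USP9Y was at least 784-fold higher in ETEC and at least 860-fold higher in PET than in CON. In all, 7 Y-linked loci had no count in any CON library, and the 16 challenged libraries included 2 with at most 1 count over these loci. In 10 libraries, the listed genes lay close to a weighted sum of 2 other libraries of the same group: CON-1, CON-2, CON-3, ETEC-1, ETEC-2, ETEC-3, ETEC-4, PET-1, PET-2 and PET-3. Their residual after fitting 2 libraries was 0.298 to 0.666 of that after fitting 1, against 0.867 to 1 for the other 14 libraries. Tests over 8 libraries per group treat these 10 as independent of the rest, so each count of changed genes is also given for the other 14.

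**Figure D1:**
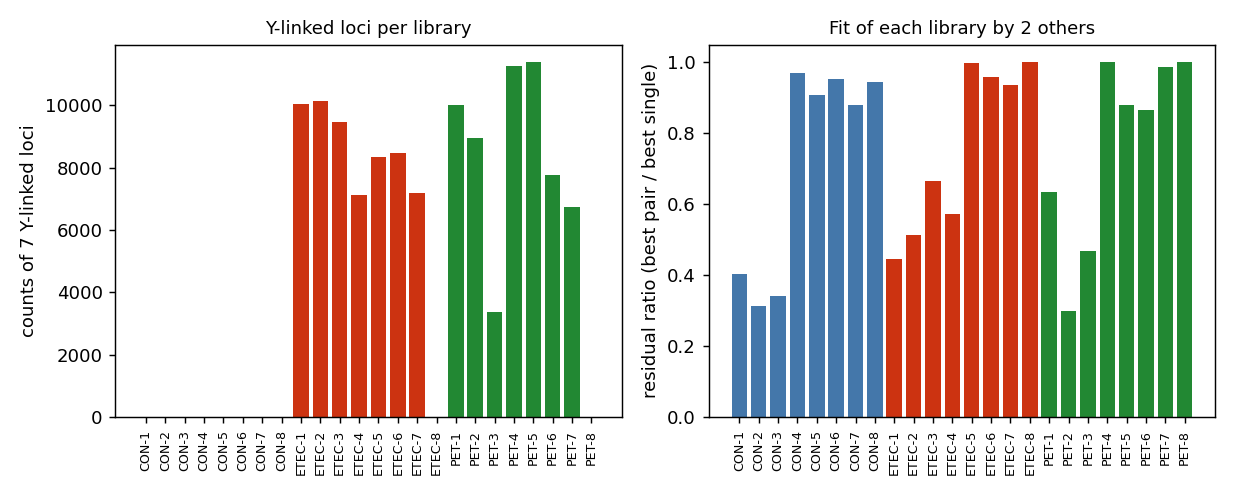
Counts of the 7 Y-linked loci per library (left), and the residual of the best fit by 2 other libraries over that of the best single library (right); colours mark CON, ETEC and PET. All CON libraries, ETEC-8 and PET-8 held at most 1 Y-linked count, and 10 libraries had a residual ratio of at most 0.666.

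The first comparison asked which genes differ between challenged and untreated calves. ANPEP, aminopeptidase N (ENSBGRG00000006001; chromosome 17, 21793317 to 21809835), stood at 319 ± 290.5 FPKM in CON and 11.96 ± 2.50 in ETEC (SD, n = 8 each), a log2 fold change of -3.91 ± 0.92 (SE) with adjusted p = 0.00166. The neutral amino acid transporter SLC6A19 was at 32.03 ± 31.3 FPKM in CON and 1.02 ± 0.494 in ETEC (log2 fold change -4.12, adjusted p = 0.00129), and the cystine and dibasic amino acid transporter SLC7A9 at 13.7 ± 17.2 FPKM in CON and 0.0821 ± 0.0399 in ETEC (log2 fold change -6.46, adjusted p = 0.000533). MTTP, which loads lipid onto nascent chylomicrons, went the other way, from 34.2 ± 10.9 FPKM in CON to 69.1 ± 6.13 in ETEC (log2 fold change 1.56 ± 0.35 (SE), adjusted p = 0.00112).

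The largest changes named here are those among called genes with a symbol and a mean of at least 1 FPKM. The largest falls were in CA7, a carbonic anhydrase (ENSBGRG00000026902; chromosome 20, 12090367 to 12100143; log2 fold change -8.62), the transcription factor OSR2 (-7.15), the sulfate transporter SLC13A1 (-6.97), the brush border peptidase CPO (-6.96), SLC7A9 and the epithelial membrane protein TMIGD1 (-6.37), with adjusted p of 0.000315 to 0.00355. OSR2 stood at 27.7 ± 26.04 FPKM in CON and 0.108 ± 0.0339 in ETEC (SD, n = 8 each). FABP6, the ileal bile acid binding protein, was at 217 ± 319.7 FPKM in CON and 2.47 ± 1.12 in ETEC (log2 fold change -5.49, adjusted p = 0.000633). Among genes with a symbol and a mean of at least 1 FPKM, the largest rises after USP9Y were in PAPPA2 and CCK. PAPPA2, a protease of insulin-like growth factor binding proteins, rose from 0.501 ± 0.191 to 2.30 ± 0.466 FPKM (log2 fold change 2.87, adjusted p = 1.79e-05). The gut hormone gene CCK had a log2 fold change of 2.77 (adjusted p = 0.00196). PROZ, the vitamin K-dependent plasma protein Z, ALDH8A1, an aldehyde dehydrogenase, and REC8, a meiotic cohesin subunit, rose by log2 fold changes of 2.61, 2.51 and 2.17, with adjusted p of 0.000533, 0.00926 and 0.000324.

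Of 11 nutrient transport genes in the table, 6 fell (SLC10A2, SLC1A1, SLC23A1, SLC34A2, SLC6A19 and SLC7A9), 2 rose (the export pump ABCC2 and the folate transporter SLC46A1) and 3 did not pass. The counts were also 6 and 2 when adjusted over the list alone, and 8 fell and 1 rose with library sizes taken from the FPKM columns. Of 5 ion and water transport genes, 3 fell and 0 rose, also when adjusted over the list alone, and 5 fell with library sizes from the FPKM columns; the chloride-bicarbonate exchanger SLC26A3 was at 21.9 ± 19.9 FPKM in CON and 1.40 ± 0.335 in ETEC (log2 fold change -3.16, adjusted p = 0.00383) and the membrane-bound carbonic anhydrase CA4 had a log2 fold change of -2.62 (adjusted p = 0.0110). Of 8 enterocyte genes, ANPEP and ENPEP fell, MTTP and ENPP3 rose and 4 did not pass, with 2 and 2 when adjusted over the list alone; by library sizes from the FPKM columns 3 fell and 1 rose. Since the table holds only genes that the authors called in these libraries, the member counts of a list are not independent evidence of its direction. After seeing the data, 11 transporter, peptidase and carbonic anhydrase genes were chosen because they were lower in ETEC with both scalings. They are called brush border genes here for short, and their geometric mean of FPKM was taken. It was 0.921 to 1.34 in the 8 ETEC libraries. CON libraries within that range were CON-4, CON-7 and CON-8 (1.05 to 1.19), and the other 5 were at 11.2 to 40.9.

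**Figure D2:**
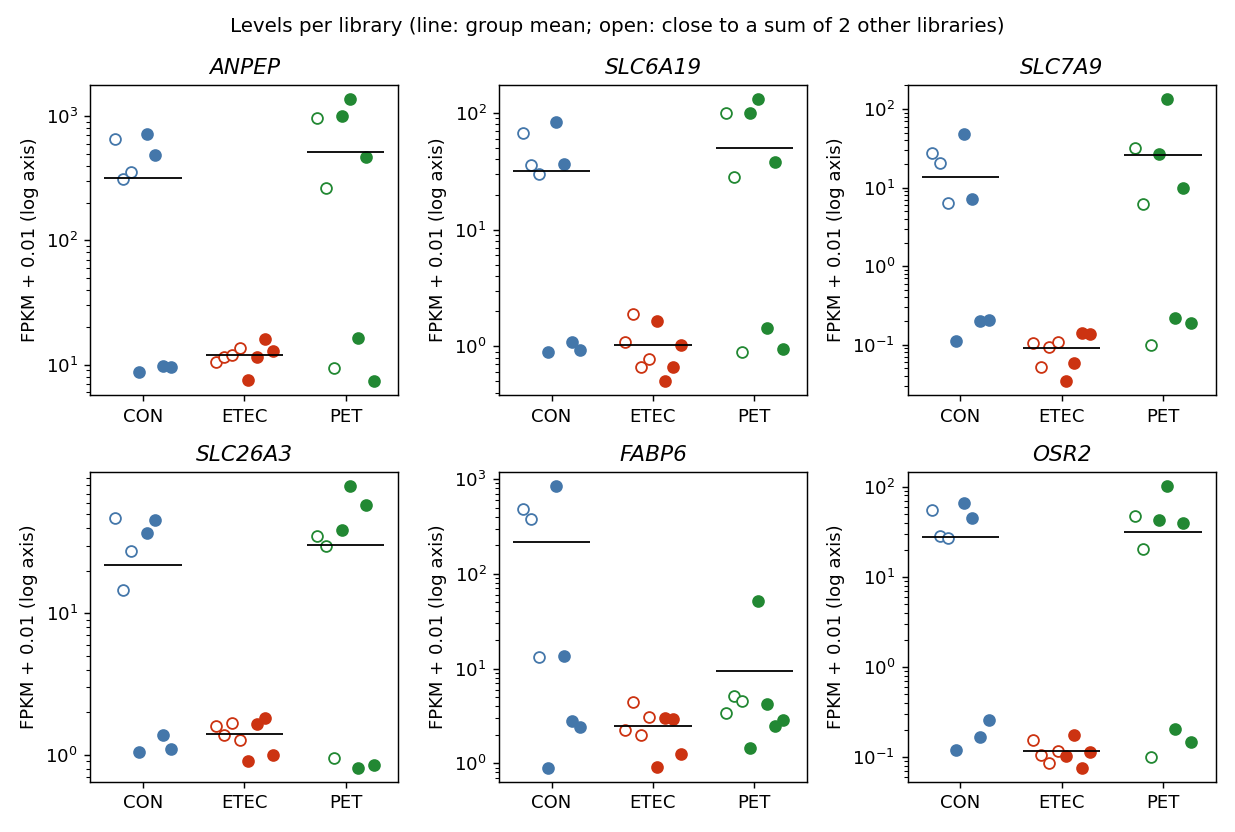
FPKM plus 0.01 on a log axis for 6 genes in each library of CON, ETEC and PET; lines are group means and open points are the 10 libraries close to a sum of 2 others. The 3 CON libraries CON-4, CON-7 and CON-8 lie near the ETEC libraries, with ANPEP at 8.72 to 9.71 FPKM against 7.53 to 16.2 in ETEC.

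The eosinophil chemoattractants CCL24 and CCL26, the 2 cytokine genes in the table, both fell, also when adjusted over the list alone; CCL24 was at 20.00 ± 18.5 FPKM in CON and 2.31 ± 0.575 in ETEC (log2 fold change -2.27, adjusted p = 0.00291) and CCL26 had a log2 fold change of -2.29 (adjusted p = 0.00322). Of 3 antimicrobial genes tested, 2 fell, also when adjusted over the list alone: the inducible nitric oxide synthase NOS2 and the iron-binding protein LTF, with log2 fold changes of -1.53 and -0.89 and adjusted p of 0.00471 and 0.0311. TLR5 and ISG15, the only members of the Toll-like receptor and interferon lists in the table, did not pass, and TLR5 fell with library sizes from the FPKM columns. The quinone reductase NQO1, a target of the stress-response factor NRF2, rose from 13.9 ± 5.31 to 27.3 ± 4.63 FPKM (log2 fold change 1.55, adjusted p = 0.000362), and the macrophage receptor TREM2 from 1.48 ± 0.382 to 2.60 ± 0.623 (log2 fold change 1.38, adjusted p = 0.000634). Among enteroendocrine genes CCK rose and NTS, neurotensin, fell (log2 fold change -1.86, adjusted p = 0.00582). For CCL24, CCL26, NOS2 and NTS, the lowest CON library lay within or below the ETEC range. These CON minima were 1.36, 3.21, 0.364 and 3.39 FPKM, against 1.59 to 3.28, 1.83 to 6.21, 0.493 to 0.907 and 3.79 to 6.84 in ETEC. LTF did not overlap, with at least 0.509 FPKM in CON and at most 0.491 in ETEC. Of 4 neutrophil markers, LTF fell and 3 did not pass, with 0 passing when adjusted over the list alone, and the T and NK cell markers GZMA and GZMM did not pass; with library sizes from the FPKM columns 3 and 2 of these fell. TFF1, a secreted trefoil peptide, rose with adjusted p = 0.0293, and the fibrinogen chain FGB fell with adjusted p = 0.0286. The FGB call was lost without CON-4 or ETEC-6 (adjusted p = 0.135 and 0.0526) and with the replicate number as a block (0.102), and the TFF1 call in 16 of 26 alternatives (adjusted p 0.000938 to 0.372). The LTF call was lost without CON-5 or ETEC-6 (adjusted p = 0.0694 and 0.0623).

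In all, edgeR called 297 of 578 genes at an adjusted p under 0.05, of which 208 were higher and 89 lower in ETEC. The second scaling, by library sizes from the FPKM columns, gave 409, of which 171 were higher and 238 lower. In the authors' deposited table, 467 genes were called, 196 of them higher and 271 lower in ETEC. Over the 14 libraries not close to a sum, edgeR called 11 genes, all higher, with 124 at an unadjusted p under 0.05, and with library sizes from the FPKM columns 0, with 153 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0526. Among named genes only USP9Y and PAPPA2 kept their calls there with TMM. DESeq2 called 66 genes over these libraries with TMM and 76 with library sizes from the FPKM columns, and limma voom 11 and 47. The fall of ANPEP had a log2 fold change of -3.59 over the 14 libraries (adjusted p = 0.185), and that of FABP6 -5.41 (adjusted p = 0.142).

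The comparison of PET with ETEC asked what the pretreatment changed in challenged calves. Among called genes with a symbol and a mean of at least 1 FPKM, SLC13A1 rose most, from 0.0220 ± 0.0116 to 13.7 ± 13.96 FPKM (SD, n = 8 each; log2 fold change 8.20 ± 1.43 (SE), adjusted p = 0.000520). Next were CA7 (log2 fold change 8.12), CPO (7.90), TMIGD1 (7.29), OSR2 (7.16) and SLC7A9 (7.13), each with an adjusted p of at most 0.00375. ANPEP was at 11.96 ± 2.50 FPKM in ETEC and 514 ± 534 in PET (log2 fold change 4.37, adjusted p = 0.00192) and the glutamyl aminopeptidase ENPEP at 2.73 ± 0.467 FPKM in ETEC and 97.2 ± 134 in PET (log2 fold change 4.00, adjusted p = 0.00173). B3GNT6, which builds core 3 O-glycans of mucins (ENSBGRG00000018932; chromosome 13, 7052108 to 7074441), was lower in PET at 0.331 ± 0.0677 against 28.2 ± 40.4 FPKM in ETEC (log2 fold change -7.03 ± 1.69 (SE), adjusted p = 0.00390). Among the ETEC libraries it was on only in ETEC-1, ETEC-3 and ETEC-6, the first 2 of which lay close to sums that include ETEC-6, and 0 PET libraries lay below all ETEC libraries. The B3GNT6 call was lost with voom (adjusted p = 0.210) and with the replicate block (0.140), and voom also lost those of CA7 (0.106) and TMIGD1 (0.309).

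Of the 11 nutrient transport genes, 8 rose, 0 fell and 3 did not pass, against 8 and 1 (SLC46A1) when adjusted over the list alone and 9 and 0 with library sizes from the FPKM columns; SLC6A19 had a log2 fold change of 4.56 (adjusted p = 0.00173). Of the 5 ion and water transport genes, 3 rose and 2 did not pass, also when adjusted over the list alone, and 5 rose by library sizes from the FPKM columns. SLC26A3 was at 30.4 ± 29.02 FPKM in PET (log2 fold change 3.54, adjusted p = 0.00396). The carbonic anhydrase CA12 was at 0.272 ± 0.0468 FPKM in ETEC and 4.43 ± 6.55 in PET (log2 fold change 2.93, adjusted p = 0.00388), with PET-5 at 19.8 and the other PET libraries at 0.101 to 5.44. Of the 8 enterocyte genes, 4 rose (ANPEP, ENPEP, MEP1A and XPNPEP2) and 4 did not pass, also when adjusted over the list alone, and 6 rose by library sizes from the FPKM columns. The geometric mean of the 11 brush border genes was within the ETEC range in PET-3, PET-6 and PET-8 (0.955 to 1.31) and 10.6 to 84.5 in the other 5 PET libraries.

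The other named falls had log2 fold changes of -3.01 for ALDH8A1, -2.42 for C10orf82, -1.90 for the dicarboxylate transporter SLC13A2, -1.80 for DDAH1, which degrades asymmetric dimethylarginine, and -1.68 for QPRT, of NAD synthesis. Their adjusted p were 0.00655, 0.0119, 0.00366, 0.0164 and 0.00451. OLFM4, a marker of crypt base stem cells, fell from 158 ± 105 to 69.2 ± 38.7 FPKM (log2 fold change -1.48, adjusted p = 0.0163), but without ETEC-8 its adjusted p was 0.0510. The interferon-induced ISG15 fell (log2 fold change -1.48, adjusted p = 0.00619); its adjusted p was 0.0582 with library sizes from the FPKM columns, 0.0529 with voom and 0.0503 without ETEC-5. NQO1 was lower in PET (log2 fold change -0.82, adjusted p = 0.0413), a call lost in 23 of 27 alternatives (adjusted p 0.00712 to 0.836). CCL24 and CCL26 did not pass over all genes, and both rose when adjusted over the list alone and with library sizes from the FPKM columns.

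In all, edgeR called 162 genes, 76 higher and 86 lower in PET. The scaling by library sizes from the FPKM columns gave 271, of which 207 were higher and 64 lower. In the authors' deposited table, 229 genes were called, 175 of them higher and 54 lower in PET. Over the 14 libraries not close to a sum, edgeR called 0 genes with either scaling, with 123 and 163 at an unadjusted p under 0.05. DESeq2 called 52 with TMM and 92 with library sizes from the FPKM columns, and limma voom 0 and 0. All named calls of this comparison were lost there by edgeR. SLC6A19 had a log2 fold change of 5.16 over the 14 libraries (adjusted p = 0.157).

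Of the 297 genes changed in ETEC vs CON, 92 changed in the opposite direction in PET against ETEC: 45 fell and then rose, among them CA7, OSR2 and ANPEP, and 47 rose and then fell, among them ALDH8A1. By library sizes from the FPKM columns there were 161 of 409, of which 136 fell and then rose and 25 rose and then fell. In the authors' deposited table, 97 genes fell in ETEC and rose in PET, and 24 rose and then fell. Both comparisons share the ETEC libraries. In 100 simulated sets of unchanged groups at most 2 genes were called in ETEC vs CON, so these sets give no value to hold against the 92. Across genes, which are not independent replicates, the correlation of the log2 fold changes had a median of -0.50 in these sets against -0.56 observed. The covariance was -2.79 observed and -0.19 in the simulated sets. With separate sets of 4 ETEC libraries in the 2 comparisons, the count over 70 splits had a median of 36 (28 to 44), the correlation of -0.53 and the covariance of -2.68. Some of these sets still share source libraries, since 4 ETEC libraries lay close to sums of others. All genes were also listed for differing between groups, with these same ETEC libraries in 2 of the 3 comparisons. The splits keep that choice and the simulated sets lack it. Neither can therefore show how much of the count, correlation or covariance comes from it. Over the 14 libraries not close to a sum, 0 genes passed in both comparisons with opposite signs in edgeR, with either scaling. This follows from the 0 genes that edgeR called there in PET vs ETEC, so it does not bear on the reversal.

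**Figure D3:**
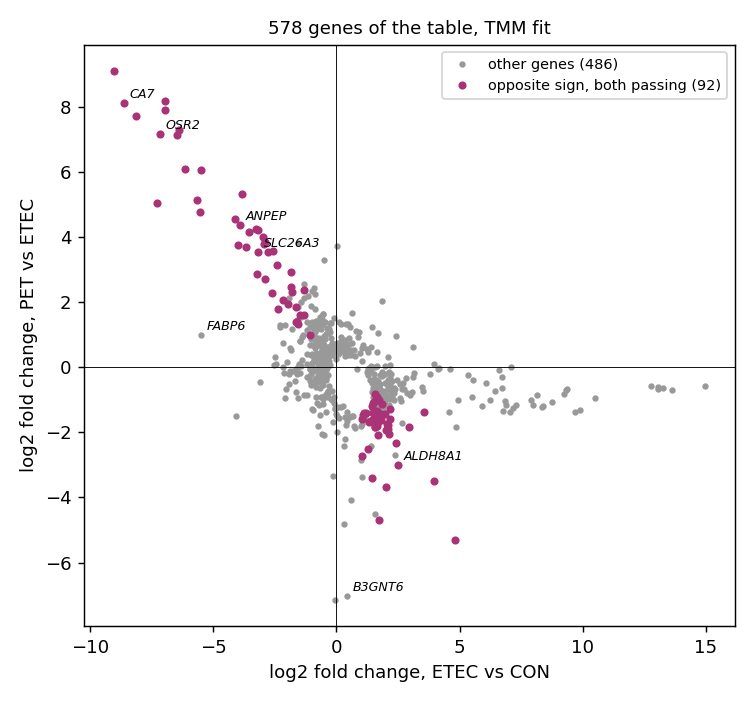
Log2 fold change of PET vs ETEC against that of ETEC vs CON for the 578 genes tested, each point a gene, in the TMM fit. The 92 genes that passed in both comparisons with opposite signs are coloured; fitted values of genes without counts in CON, at the far right, depend on the prior count and are not measured folds.

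The comparison of PET with CON asked how pretreated and challenged calves differ from untreated ones. CDH26, a cadherin (ENSBGRG00000024093; chromosome 12, 49832557 to 49884473), was at 0.461 ± 0.229 FPKM in CON and 5.55 ± 5.96 in PET (SD, n = 8 each), a log2 fold change of 3.73 ± 0.63 (SE) with adjusted p = 0.000163. The intestinal alkaline sphingomyelinase ENPP7 was at 1.21 ± 0.619 FPKM in CON and 26.8 ± 48.2 in PET (log2 fold change 3.90, adjusted p = 0.00714), with PET-1 and PET-4 at 91.9 and 116. PET-1 lay close to a sum in which PET-4 had 89.9% of the weight. PAPPA2, CCK and C3orf85 rose with log2 fold changes of 2.09, 2.09 and 2.00 and adjusted p of 0.000362, 0.0147 and 0.00101. B3GNT6 was at 26.9 ± 38.2 FPKM in CON and 0.331 ± 0.0677 in PET (log2 fold change -6.60, adjusted p = 0.00448). FABP6 was at 217 ± 319.7 FPKM in CON and 9.39 ± 16.96 in PET (log2 fold change -4.51, adjusted p = 0.00350), with PET-5 at 51.3 and the other PET libraries at 1.43 to 5.08. In CON, B3GNT6 was on only in CON-3, CON-4 and CON-8, and CON-3 lay close to a sum of CON-4 and CON-6.

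Of the 11 nutrient transport genes, the peptide transporter SLC15A1 rose (log2 fold change 0.97, adjusted p = 0.0335) and 10 did not pass, and 0 passed when adjusted over the list alone. None of the 5 ion and water transport genes passed. The liver-type plasma protein genes FGB, FGG and APOA2 fell with log2 fold changes of -2.36, -2.28 and -2.12 and adjusted p of 0.0447, 0.0497 and 0.0361. CON-4 held the highest level of each, and without it the adjusted p were 0.293, 0.388 and 0.229. The natural killer cell receptor KLRF1 fell from 1.90 ± 0.368 to 0.692 ± 0.305 FPKM (log2 fold change -1.46, adjusted p = 0.000622) and ISG15 from 20.4 ± 8.63 to 6.88 ± 1.37 (log2 fold change -1.46, adjusted p = 0.00567).

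TREM2 rose (log2 fold change 0.99, adjusted p = 0.0101), as did CYP1A1, a xenobiotic-metabolising cytochrome P450 (log2 fold change 1.82, adjusted p = 0.0184). NOS2 and LTF fell, with adjusted p of 0.0108 and 0.0210, and NTS fell with adjusted p = 0.0439. With library sizes from the FPKM columns, LTF, NTS, FGB and FGG no longer passed (adjusted p = 0.143, 0.0505, 0.0564 and 0.0635). Leaving out 1 library ended the CCK call (without PET-8, adjusted p = 0.0697), the NOS2 call (without CON-2, 0.0573) and the SLC15A1 call (without CON-5 or PET-4, 0.0598 and 0.0783). Of the 20 named calls, voom lost 11 and the replicate block 10, and 8 of 19 were lost with only the 2 groups compared. B3GNT6 had an adjusted p of 0.340 with voom and 0.160 with the block, ENPP7 0.429 and 0.408, CYP1A1 0.503 and 0.172, CCK 0.0622 and 0.194, and FABP6 0.0508 with voom. The voom log2 fold changes of ENPP7 and CYP1A1 were 0.87 and 0.48, and the NOS2 call was also lost with only the 2 groups (adjusted p = 0.0642). The calls of NTS, FGG, FGB, LTF and APOA2 were lost in 19 of 26, 17 of 26, 16 of 26, 14 of 26 and 13 of 26 alternatives, most of them the removal of 1 library.

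In all, edgeR called 224 genes, 136 higher and 88 lower in PET than in CON. By library sizes from the FPKM columns there were 240, of which 151 were higher and 89 lower. In the authors' deposited table, 199 genes were called, 117 of them higher and 82 lower in PET. Over the 14 libraries not close to a sum, edgeR called 13 genes, 11 higher and 2 lower, and with library sizes from the FPKM columns 10, of which 9 were higher and 1 lower. Among named genes CDH26 and USP9Y kept their calls in both. DESeq2 called 66 and 78 genes over these libraries, and limma voom 3 and 3. The same direction was called in ETEC and in PET against CON for 128 genes, 107 higher, among them PAPPA2, CCK and TREM2, and 21 lower, among them FABP6, NOS2 and NTS. Independent lists would share 48.9 and 13.6. USP9Y is also among the 107, and no CON library held counts of the Y-linked loci described above. A shared rise against CON therefore need not be a response to the challenge. With separate sets of 4 CON libraries the median was 59 (45 to 83): 50.5 higher, where independent lists would share 18.4, and 6.5 lower, where they would share 5.53. Genes called in opposite directions there numbered 0 to 34. Some of these sets still share source libraries, since 3 CON libraries lay close to sums of others, and all of them lack Y-linked counts. All genes were also listed for differing between groups, with these same CON libraries in 2 of the 3 comparisons. The splits keep that choice and cannot show how much of the overlap comes from it. With library sizes from the FPKM columns the overlap was 151, of which 101 were higher and 50 lower, where independent lists would share 44.7 and 36.6. These expected numbers are over the 578 genes tested, which were listed for being called, and so are higher than over all genes of the genome.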

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

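All tests of explanations here were chosen after the results were seen, except the regroupings of the libraries; the gene lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined.

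The first pattern is the absence of Y-linked counts in CON. Too few reads in the CON libraries are argued against by USP9Y, for which 1939 counts would be expected in the shallowest CON library at the ETEC level. That the challenge switched these loci on is argued against by the 2 challenged libraries, ETEC-8 and PET-8, with at most 1 count over them. The 7 loci were chosen as Y-linked loci without counts in CON, so their joint absence there was set by the choice. Another locus listed on the Y chromosome had counts in CON and was left out by this choice. In all 16 challenged libraries the 7 loci were all on or all off together. A candidate explanation is that the CON calves were female and most of the others male. Sex would then be nearly confounded with the challenge, and part of the differences from CON may reflect it, while ETEC and PET each hold 1 library with at most 1 Y-linked count.

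The second pattern is the 10 libraries close to a weighted sum of 2 others of their group. For CON-1 these were CON-5 and CON-6, for CON-2 CON-5 and CON-7, for CON-3 CON-4 and CON-6, for ETEC-1 ETEC-5 and ETEC-6, for ETEC-2 ETEC-5 and ETEC-7, for ETEC-3 ETEC-6 and ETEC-8, for ETEC-4 ETEC-7 and ETEC-8, for PET-1 PET-4 and PET-5, for PET-2 PET-6 and PET-7, and for PET-3 PET-6 and PET-8. The Y-linked level bears only on 3 of them, ETEC-3, ETEC-4 and PET-3, where only 1 of the 2 sources held more than 1 Y-linked count. For the rest, both sources held or both lacked such counts, so the level cannot tell. It was 76.0%, 61.6% and 48.6% of the full level in ETEC-3, ETEC-4 and PET-3. In the 7 libraries with Y-linked counts not close to a sum it was 96.3% to 127%. For these 3 libraries, the lower values argue against separate animals that happen to resemble each other. RNA or reads of 2 animals in 1 library may explain these values: weights fitted outside the Y chromosome predicted 86.2%, 51.0% and 47.1%, with a largest log2 ratio of 0.27 between measured and predicted. No biological explanation was tested, and whether any mixing arose from tissue, RNA, libraries or reads stays open.

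The third pattern is the low mean of the 11 brush border genes, chosen for being lower in ETEC, in all ETEC libraries. The challenge alone is argued against by 3 CON libraries, CON-4, CON-7 and CON-8, within the ETEC range; of the libraries not close to a sum, 3 of 5 CON, 2 of 5 PET and all 4 ETEC libraries lay there. A lower share of epithelial cells in the ETEC tissue would lower such genes together, but 2 enterocyte or transport genes, MTTP and SLC46A1, were higher in ETEC with both scalings. These 2 cannot exclude a lower share, because only 8 of 36 enterocyte list genes are in the table, all listed for differing. SLC46A1 is also among the proximal markers below. In a comparison of groups, pieces taken at different positions along the intestine cannot be told apart from an effect of the groups, since no label gives a position. Within CON and PET the mean of the 11 genes varied with that of distal markers (FABP6, SLC10A2, NTS and HOXB6, as log2 of FPKM plus 0.1). The distal mean was 0.92 to 1.58 in CON-4, CON-7 and CON-8 and 3.28 to 6.63 in the other CON libraries. It was 1.23 to 1.64 in PET-3, PET-6 and PET-8 and 2.54 to 5.94 in the other PET libraries. FABP6 itself was high only in PET-5 among the PET libraries, at 51.3 FPKM. In the others it was 1.43 to 5.08 FPKM, near the 0.912 to 4.39 of the ETEC libraries. Whether position caused the variation of the 11 genes was not tested. Comparing 1 library with 1 other cannot decide this: of 4 proximal markers (ONECUT2, ADA, SLC46A1 and CCK, of 10 listed), 4 were lower in CON-5, with the highest mean of distal markers (FABP6, SLC10A2, NTS and HOXB6, of 8 listed), than in CON-4, with the lowest, and 3 in PET-5 than in PET-6; SLC10A2 is also among the 11 genes, and the mean log2 of FPKM plus 0.1 of the proximal markers, of which ADA, SLC46A1 and CCK passed as higher in ETEC, was 1.02 to 3.32 in CON, 3.42 to 4.31 in ETEC and 0.33 to 5.12 in PET.

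For the number of genes changed, 100 splits of the 16 libraries of each comparison were drawn, the real split included. In each comparison 1 split, the real one, gave as many genes; the real values were 297, 162 and 224 and the highest others 106, 71 and 163. These counts cannot exclude chance, because the genes were listed for differing between exactly these groups.

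Single libraries stood far from the rest of their group in 20 of 140 sets of 8 values of a named gene. Chance gives about 5% only for independent, normally distributed values. These FPKM were taken without logarithms and some were strongly skewed, such as TMIGD1 in PET at 43.7 ± 106 (SD). The sets also share libraries, and PET-5 alone gave 8 of the 20. The 5% is thus no reference for this number. PET-5 was highest of its group for OSR2 (102 FPKM), SLC7A9 (134), TMIGD1 (305), FABP6 (51.3), CCL24 (35.2), CA4 (11.01), CA12 (19.8) and CYP1A1 (16.1). ETEC-8 was lowest for USP9Y (0) and NTS (3.79) and highest for CPO (0.0699) and OLFM4 (396). ETEC-5 was highest for REC8 (16.5), FGB (4.18) and FGG (2.83). SLC13A1 was highest in ETEC-2 (0.0469), C3orf85 in ETEC-3 (9.73), TMIGD1 in CON-5 (76.3), FGG in CON-4 (22.1) and TFF1 in PET-8 (5.69).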

How the results depend on the processing

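The scaling by library sizes from the FPKM columns, the 14 libraries, both together, and leaving out ETEC-8 with PET-8 were chosen after the results were seen. No named gene reversed its direction under any alternative. Over the 14 libraries ETEC vs CON gave 11 genes (11 higher, 0 lower), PET vs ETEC 0 (0 and 0), PET vs CON 13 (11 and 2), with 0 genes reversed between comparisons and an overlap of 8. With library sizes from the FPKM columns as well, these were 0 (0 and 0), 0 (0 and 0), 10 (9 and 1), 0 and 0. Fewer samples are part of this: 40 random sets of the same sizes gave medians of 132.5, 16 and 110.5 genes with TMM (37 to 299, 0 to 122 and 29 to 246), and 0, 3 and 0 of them gave as few as the 14 libraries. With library sizes from the FPKM columns the medians were 145.5, 8 and 120 (30 to 347, 0 to 214 and 46 to 252), and 0, 7 and 0 sets gave as few. Those sets held 3 to 9 libraries close to a sum.

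The number lower in ETEC vs CON was 89, and 157 with DESeq2 size factors, 159 without the filter, 155 with voom, 194 with only the groups compared and 238 with library sizes from the FPKM columns. The number higher in PET vs ETEC was 76, and 117, 146, 49, 123 and 207 in the same order, with 152 without ETEC-8 and PET-8; the number lower was 134 with voom, against 86. With library sizes from the FPKM columns, PET vs ETEC gave 271 genes and 161 genes were reversed between comparisons. PET vs CON gave 124 genes (83 higher and 41 lower) with only the groups compared. All counts stayed within 1.5 times with the DESeq2 test and with the 2-fold threshold. Apart from the scaling and the fewer samples, the cause was not tested.

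Leaving out each library in turn gave 275 to 375 genes in ETEC vs CON (167 to 214 higher, 76 to 200 lower), 138 to 231 in PET vs ETEC (65 to 159 higher, 49 to 114 lower), 194 to 267 in PET vs CON (126 to 183 higher, 55 to 101 lower) and 73 to 100 reversed between comparisons. Counts moved by over 1.5 times for the number lower in ETEC vs CON (134 without CON-2, 139 without CON-8, 200 without ETEC-5, 136 without ETEC-8), the number higher in PET vs ETEC (116, 119, 116, 130 and 120 without ETEC-2, ETEC-4, ETEC-5, ETEC-7 and ETEC-8; 150, 158, 151 and 159 without PET-1, PET-3, PET-5 and PET-6), the number lower there (56, 56, 49, 54 and 54 without ETEC-3, ETEC-5, PET-1, PET-4 and PET-5) and the number lower in PET vs CON (55 without PET-1). Of the named calls, 23 of 448, 18 of 336 and 52 of 320 were lost in ETEC vs CON, PET vs ETEC and PET vs CON.

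With the replicate number as a replicate block, ETEC vs CON gave 275 genes, PET vs ETEC 136 (41 higher), PET vs CON 167, 89 genes were reversed between comparisons and 92 overlapped. The labels state no pairing of same-numbered libraries, and 9 of 24 correlations of their deviations exceeded 0.1 (-0.36 to 0.60). In 6 of the 24 comparisons of a library with another group the best match had its own number. These were 4 of PET with ETEC, 2 of PET with CON and 0 of ETEC with CON. The numbers carried some structure: libraries 1, 2 and 3 were close to a sum in every group. ETEC-8 and PET-8, both with at most 1 Y-linked count, correlated at 0.45. What the numbers stand for cannot be told from the labels. The list tests with an estimated correlation and with the block were not run, because the list test itself was not run. Depth limits low genes: 61 genes had too few counts to be tested.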

Other observations

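The values in this part were chosen after the results were seen. Some genes of liver and plasma proteins were highest in CON-4: ALB, serum albumin, stood at 53.3 FPKM there, HPX, which binds haem, at 17.7, and AMBP, a plasma protease inhibitor, at 10.9. The plasma protein gene PROZ was not among them, with at most 1.17 FPKM in CON and 0.515 to 4.02 in ETEC. CON-3 and CON-2 followed, with ALB at 24.4 and 19.8 FPKM, and no ETEC or PET library exceeded 8.89. B3GNT6 was on in 6 libraries, CON-3, CON-4, CON-8, ETEC-1, ETEC-3 and ETEC-6, with 45.6 to 96.9 FPKM, and at most 0.874 in the others, all PET libraries included. Of these, CON-3 lay close to a sum that includes CON-4, and ETEC-1 and ETEC-3 to sums that include ETEC-6. The PET libraries also differed among themselves. In PET-1 and PET-4 the peptide transporter SLC15A1 was at 152 and 187 FPKM and the cytotoxic granule protease GZMA at 103 and 128. ADA, adenosine deaminase, was at 129.7 in PET-3 and 230.0 in PET-8 and at most 8.86 in the other PET libraries. PET-1 lay close to a sum in which PET-4 had 89.9% of the weight, and PET-3 to one in which PET-8 had 54.6%. The members of each pair are thus not independent.

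Outside the Y chromosome, 27 loci on 20 chromosomes passed as higher in ETEC than in CON and had at most 3 counts in every CON library; 25 of them have no annotation. Of these loci, 5 on 5 chromosomes reached 20 counts in exactly ETEC-1, ETEC-2, ETEC-3, ETEC-5, ETEC-6, PET-2, PET-3, PET-5 and PET-6, and 4 on 4 chromosomes did so in the same libraries except PET-3. Another 3 loci on 3 chromosomes did so in all ETEC libraries and in PET-1, PET-2, PET-3, PET-4, PET-6 and PET-7. ETEC-1, ETEC-2 and ETEC-3 lay close to sums that include ETEC-5 or ETEC-6, and PET-2 and PET-3 to sums that include PET-6. The libraries that share a pattern are thus not all independent.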
